A study of Homo sapiens with 9 samples.

How the data were processed

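RNA abundance was measured on 9 Affymetrix HG-U133 Plus 2 arrays in the Ewing sarcoma line TC-71 and in 3 lines selected from it for resistance to agents against the IGF-1 receptor. The deposited values were log2 expression levels per probe set, summarised with RMA in the affy package per the submitters' processing notes, with versions not given in the sources used here. Total RNA was extracted with TRIzol and 2 µg per sample was labelled with biotin. The cells were kept in Iscove medium with 10% serum.

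There were 3 TC-71 samples with 1 array each and 2 arrays for each of the 3 resistant lines. The 2 arrays of a line were technical replicates per the labels, so their values were averaged and each line counted as 1 sample, which gave 6 samples. The level at which the technical replicates were split, culture, RNA or labelled target, was not given in the sources used here. With 1 sample per line, the spread in the single-line comparisons came from the TC-71 samples and the lone line was assumed to vary like TC-71. All p-values measure only the spread between these samples. The number of arrays limits the precision of every value.

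The 62 control probe sets were left out, which left 54613. Of these, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none. Symbols were checked by gene identifier against a RefSeq gene table for assembly GRCh38.p14, in which 41037 of the single-symbol probe sets were found and 0 symbols were updated. A single-symbol probe set was kept where at least 2 of the 9 arrays reached 5 on the log2 scale, which kept 26952. Each gene was represented by its kept probe set with the highest mean over the 9 arrays. The _x_at probe sets, prone to cross-hybridisation, were used only where the gene had no other. This gave 14181 genes. Probe sets with no symbol or several symbols were tested apart from the genes.

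Differences were tested with limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 14181 genes and a threshold of 0.05 on the adjusted p. A fit with 4 groups served the comparisons of TC/AEW, TC/AVE and TC/CP singly with TC-71, of TC/AEW with the mean of the 2 antibody-selected lines, and of TC/AVE with TC/CP. It had 2 residual degrees of freedom and 3.00 prior degrees of freedom. A fit with 2 groups, 3 TC-71 samples and 3 lines, served the comparison of the resistant lines in common, with 4 residual and 3.06 prior degrees of freedom. Without any change, a share of 0.05 of all genes tested is expected at an unadjusted p under 0.05. Counts of genes at that p lay below this share in TC/AEW, in TC/CP and in TC/AEW against the antibody-selected lines. Counts of probe sets with no symbol or several lay below it in every comparison except the lines in common. Errors given with log2 differences of genes are moderated standard errors of these fits. The spread given with within-year differences of list means is the SD of a difference between 2 TC-71 samples, from the SD of the list mean over the 3. The 39 gene lists, holding 818 measured genes of which 71 were in more than 1 list, were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation. The lists, the comparisons, the threshold, the filter, the rule for named genes and all alternatives except the within-year difference of gene lists were chosen before the data were examined.

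The named genes followed 1 rule. Among genes past the threshold with every array of a line beyond all 3 TC-71 arrays, the 8 largest rises and 8 largest falls were to be named, or 6 and 6 between lines. Where fewer than 4 passed in a direction, the 4 with the largest moderated statistic in that direction were given as values. Always included were IGF1R, INSR, IGF2R, IGF1, IGF2, IRS1, IRS2, IGFBP3, IGFBP5 and FLI1, and up to 4 members per gene list with the largest absolute difference. Genes named outside this rule are marked in the text as chosen after their values were seen.

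A year mark in the labels, whose meaning is not stated, splits the arrays into 3 sets. The first set held TC-71 sample 1, the second held TC-71 sample 2 with TC/AEW and TC/AVE, and the third held TC-71 sample 3 with TC/CP. A within-year difference was therefore taken as the line minus the TC-71 sample of the same set, without a test. It was planned for genes and added for gene lists after the data were seen. For the lines in common it was the mean of the 3 within-year differences, and between lines it was the difference between them.

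The alternatives tried were no filter on dim probe sets, a filter at 6 on the log2 scale, the mean of a gene's probe sets, no probe sets prone to cross-hybridisation, cyclic loess normalisation, a mean-variance trend, the 9 arrays taken as samples with and without a replicate block, the year mark as a block, the lines in common as a contrast in the 4-group fit, duplicateCorrelation over the RNA source, the estimated correlation for lists, and leaving out each array, TC-71 sample and line in turn. The procedure was tested on simulated data with the TC-71 gene means and spreads drawn from the prior that limma estimated on these samples. That prior came from the 4-group fit, where only the TC-71 samples give spread. Differences between the resistant lines were therefore not simulated, and the rates for the lines in common may be too high. Simulated genes varied independently, so the list rates do not cover correlated lists, such as interferon response (estimated correlation 0.36 in the 4-group fit). Over 20 simulations, 0.4% of changes of 1 on the log2 scale, 39.3% of changes of 2 and 79.8% of changes of 3 were called in the comparison of a single line, and 37.3%, 87.4% and 96.2% in the comparison of the lines in common. A list raised by 0.5 was called in 100% of simulations with the preset correlation, and with the estimated correlation in 0% for a single line and 85% for the lines in common.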

Results

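Steady-state RNA was measured in TC-71, a Ewing sarcoma cell line that carries the EWSR1-FLI1 fusion, and in 3 lines derived from it by exposure for 6 months to increasing concentrations of an agent against the IGF-1 receptor. TC/AEW was selected with NVP-AEW541, a small-molecule inhibitor of the receptor's kinase, at up to 5 µM. TC/AVE was selected with the antibody AVE1642 at up to 10 µg/ml, and TC/CP with the antibody figitumumab, for which the highest concentration was not given in the sources used here. There were 3 TC-71 samples with 1 array each and 2 technical replicate arrays per resistant line, averaged into 1 sample. Levels are on the log2 scale, TC-71 values are means ± SD (n = 3), and differences are means ± SE on the log2 scale. The resistant lines had no biological replicates. A level under 5, the filter applied to probe sets, is taken as near background. A difference from such a level is a lower bound on its size, and no fold is given for it. Background may reach above 5, since the blood marker HBB read between 5.74 and 6.02 in the TC-71 samples. Folds printed for genes with a level under 6 on one side, such as COL16A1, CCND2, SPRY4 and SOX11, may thus be lower bounds too.

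The arrays were alike in distribution, with medians from 5.39 to 5.45. Across all 14181 genes, which are not independent replicates, the 2 arrays of TC/AEW, TC/AVE and TC/CP correlated at 0.996, 0.998 and 0.997. The TC-71 samples lay further apart, at 0.962 (samples 1 and 2), 0.979 (samples 1 and 3) and 0.983 (samples 2 and 3). TC-71 sample 2 correlated with the 2 TC/AEW arrays, of the same year mark, at 0.982 and 0.985, much as it did with TC-71 sample 3. The first principal component held 33.3% of the variance and the second 29.1%. TC/AVE and TC-71 sample 1 lay at opposite ends of the first and TC/CP lay at one end of the second. Because a year mark in the labels tied each line to 1 TC-71 sample, within-year differences stand beside most of the pooled ones.

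None of the named genes of the IGF pathway passed the threshold in any comparison, in single-line tests that called 0.4% of simulated changes of 1 on the log2 scale. IGF1R, the target of all 3 agents, stood at 9.30 ± 0.09 in TC-71 and at 9.18, 9.58 and 8.99 in TC/AEW, TC/AVE and TC/CP. INSR, the insulin receptor, differed by 0.49 in TC/AEW, 1.02 in TC/AVE and -0.17 in TC/CP, and within year by 0.19, 0.72 and -0.29. IGF1, which encodes a ligand, differed by 0.42, -0.03 and -0.70, and within year by 0.26, -0.19 and -0.76. IRS2, a docking protein of both receptors, had values of 11.86, 11.66 and 11.17 against 12.02 ± 0.09 in TC-71, with within-year differences of -0.06, -0.26 and -0.88. IGFBP5, a secreted IGF-binding protein, was 1.13 ± 0.31 higher in TC/AVE and differed by 0.65 in TC/AEW and -0.33 in TC/CP, and within year by 1.27, 0.79 and -0.70 in the same order. IGF2R and IRS1 differed by at most -0.48 (IGF2R in TC/AVE, -0.81 within year) in any line, IGFBP3 lay under 5 in TC-71 and all lines, and FLI1, whose 3' part is in the fusion, differed by 0.08, 0.19 and 0.71. The list of IGF receptors and ligands had an adjusted p of 0.666, 0.750 and 0.375 in TC/AEW, TC/AVE and TC/CP and of 0.953 in the lines in common. IGF2 was read only by probe sets shared with INS-IGF2 and was not tested as a gene.

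The resistant lines in common were set against TC-71 to find expression that went with resistance whatever the agent. The labels name no TC-71 sample kept alongside for the 6 months of selection. Resistance thus cannot be told apart from time in culture in this comparison. In the test of the lines in common, 3 genes passed over all genes, each of them lower in all 3 lines. COL16A1, a fibril-associated collagen, stood at 8.34 ± 0.53 in TC-71 and at 5.42, 5.26 and 5.35 in TC/AEW, TC/AVE and TC/CP, and fell by 2.99 ± 0.26 (7.96-fold, adjusted p = 0.0359 by limma). HSD17B2, which oxidises estradiol and testosterone to weaker steroids, fell by at least 2.78 ± 0.22 (adjusted p = 0.0322), from 7.08 ± 0.38 to levels between 4.03 and 4.45, near background. DACT2, a regulator of WNT and TGF-beta signalling, fell by 1.63 ± 0.13 (3.09-fold, adjusted p = 0.0322). PRPH, the neuronal intermediate filament peripherin, had a larger difference, -3.77 ± 0.36 (13.6-fold lower), and stood just outside the threshold at adjusted p = 0.0526. Within year the 4 genes differed by -2.64, -2.79, -1.61 and -3.55. With the year mark as a block no gene was called, nor when any TC-71 sample or line was left out.

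No gene rose past the threshold in the lines in common. The 4 highest ranked were BEND4 (1.70 ± 0.20), PNPLA3 (1.76 ± 0.22), GRAMD1C (1.61 ± 0.21) and HOMER2 (1.41 ± 0.18), with adjusted p from 0.112 to 0.128 and within-year differences of 1.61, 1.56, 1.36 and 1.33. GRAMD1C stood at 3.81 in TC-71, so its differences are lower bounds. PNPLA3 encodes a lipase of lipid droplets, GRAMD1C a carrier of cholesterol between membranes and HOMER2 a synaptic scaffold. Among members of the gene lists, the neuropeptide precursor SCG2 was 2.36 ± 0.52 higher (1.81 within year) and the collagen-binding integrin subunit ITGA2 was 1.59 ± 0.30 higher (1.19 within year). Of other receptor tyrosine kinases 18 were higher and 20 lower (median -0.02, adjusted p = 0.684), with ALK at -0.93 ± 0.16 (-0.92 within year) and PDGFRB at -0.89 within year. KCNE3, LIPI and FCGRT, listed as induced by EWS-FLI1, had differences of -1.32, -1.55 and -1.26 (-1.03, -1.35 and -1.06 within year), while 22 of the 41 measured genes of that list were higher and 19 lower (adjusted p = 0.684). The drug-oxidising enzyme CYP3A5 (at least 1.26 ± 0.15 lower, -1.28 within year, with all 3 lines under 5) and the BCL2 relative BOK (-1.53 ± 0.33, -1.08 within year) were also lower. None of these genes passed over all genes, and ITGA2, CYP3A5, LIPI, SCG2, ALK, PDGFRB, FCGRT and KCNE3 passed when adjusted over the list alone.

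The lists of sterol synthesis and interferon-response genes were called higher in the lines in common. Of 25 genes of cholesterol and lipid synthesis, 22 were higher and 3 lower, with a median of 0.32 (adjusted p = 4.65e-06, and adjusted p = 0.692 with an estimated correlation). INSIG1, which holds the sterol sensor in the endoplasmic reticulum, was 1.33 ± 0.26 higher, HMGCS1, at the entry to the pathway, 1.15 ± 0.20 and MSMO1, a sterol oxidase, 0.97 ± 0.17, with 1.25, 1.15 and 0.96 within year. The count past the threshold was 0 of these genes over all genes and 6 adjusted over the list alone (HMGCS1, INSIG1, MSMO1, SC5D, SQLE and STARD4). The list mean was nearly equal in the 3 TC-71 samples (SD 0.01) and lay 0.34, 0.55 and 0.24 above them in TC/AEW, TC/AVE and TC/CP, or 0.35, 0.56 and 0.24 within year, and in TC/CP alone the list was not called (adjusted p = 0.0901). Of 24 interferon-response genes, 22 were higher, with a median of 0.50 (adjusted p = 2.03e-09, and adjusted p = 0.555 with an estimated correlation). IFIT2, which binds viral RNA, was 2.40 ± 0.82 higher, and IFIT1 1.88 ± 0.55, with 2.20 and 1.44 within year. IFIH1, a sensor of double-stranded RNA, stood at 4.10 in TC-71, near background, and at 6.39, 6.06 and 5.14 in the lines. Here the count was 0 over all genes and 6 adjusted over the list alone. The list mean lay 0.98, 0.39 and 0.86 above TC-71 in TC/AEW, TC/AVE and TC/CP, and 0.72, 0.13 and 0.87 within year. The mean of the blood and immune cell markers stayed near TC-71 in the same samples, at 0.04, -0.06 and -0.15 in TC/AEW, TC/AVE and TC/CP.

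Also called in the lines in common were 4 further lists, all higher. Immediate early and stress genes had 16 of 18 members higher (median 0.30, adjusted p = 3.17e-04, and adjusted p = 0.401 with an estimated correlation), with IER3 at 1.14 (0.87 within year). Hypoxia and glycolysis genes had 24 of 30 higher (median 0.12, adjusted p = 0.00116, and adjusted p = 0.440 with an estimated correlation), with the prolyl hydroxylase P4HA2 at 1.01 (0.58 within year). Antigen presentation genes had 13 of 15 higher (median 0.28) and genes induced by ERK signalling 21 of 27 (median 0.26), both with adjusted p = 0.00665 and adjusted p = 0.760 with an estimated correlation. HLA-C (0.89, 0.82 within year) and HLA-B (0.82, 0.59 within year) led the first, and the transcription factors ETV5 (1.36, 0.72 within year) and FOSL1 (1.18, 1.22 within year) the second. In these 4 lists the count was 0 over all genes and 0 adjusted over the list alone. Antigen presentation was no longer called without TC-71 sample 3 (adjusted p = 0.0683) or without the TC/AVE line (0.196), nor were ERK-induced genes without TC-71 sample 3 (0.0618) or the TC/CP line (0.258). With no _x_at or _s_at probe sets, immediate early genes (adjusted p = 0.102), antigen presentation (0.282) and ERK-induced genes (0.236) were no longer called. Lists not called had adjusted p from 0.0939 to 0.953, and 9 of them differed in sign between median, mean and test, such as neural differentiation genes with a median of -0.06 and a mean of 0.07.

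**Figure D1:**
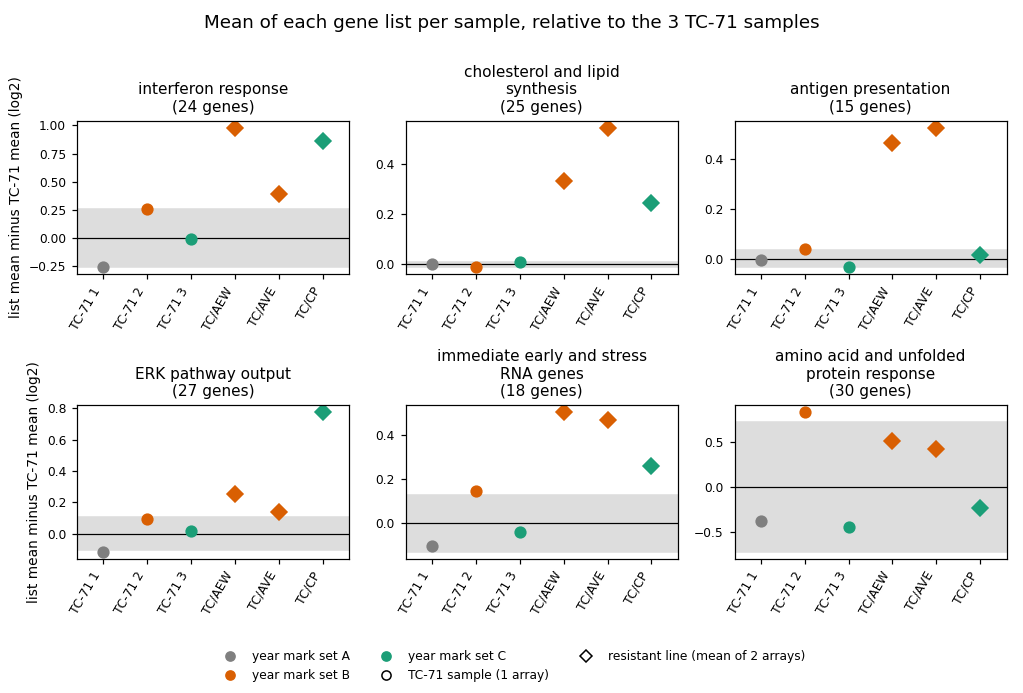
Mean log2 level of 6 gene lists in each of the 6 samples minus the mean of the 3 TC-71 samples, with colour giving the year mark set, the line the TC-71 mean and the grey band its SD. The cholesterol list lay above all TC-71 samples in all 3 lines (0.34, 0.55 and 0.24), while the amino acid and unfolded protein response list was highest in TC-71 sample 2 (0.83).

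In the lines in common, 226 genes were at least 2-fold apart from TC-71, 154 higher and 72 lower. Over all genes, every array of the lines lay beyond all 3 TC-71 arrays in 9.38%. The chance share is 10% for 3 samples against 3, and lower where both arrays of each line must lie beyond. Within year 183 genes were 2-fold apart, 81 higher and 102 lower. Without TC-71 sample 2 the count was 376. The 3 called genes were few beside 1187 genes at an unadjusted p under 0.05. A share of 0.05 of all 14181 genes is expected there without any change, which the 1187 exceeded. The number called was 0 when any TC-71 sample or any line was left out and 0 with the year mark as a block, and 5 without TC/AEW array 2, TC/AVE array 1, TC/CP array 1 or TC/CP array 2. No gene was called in all 3 single-line comparisons. At least 2-fold, 48 genes were higher in all 3 lines and 26 lower, against simulated means of 1.58 and 1.61 for unchanged lines set against the same TC-71 samples. Across genes, which are not independent replicates, the log2 differences of TC/AEW and TC/AVE correlated at 0.561, those of TC/AEW and TC/CP at 0.489 and those of TC/AVE and TC/CP at 0.355, against simulated means of 0.251, 0.249 and 0.250 from the shared TC-71 samples alone. TC/AEW and TC/AVE also share a year mark with TC-71 sample 2, which the simulations did not model.

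TC/AEW was set against TC-71 to see what the line selected with the kinase inhibitor carried. CCND2, a D-type cyclin that drives entry into S phase, stood at 8.82 against 5.46 ± 0.50 in TC-71 (3.36 ± 0.41 higher, 10.3-fold, adjusted p = 0.709). The actin regulators HCLS1 (2.76 ± 0.26) and WASF3 (2.44 ± 0.28) ranked highest, with the scramblase PLSCR4 (2.17 ± 0.26) and the membrane protein CMTM8 (1.95 ± 0.24). The lowest ranked were SUSD5 (-2.35 ± 0.23), HSD17B2 (-3.05 ± 0.34), the carbonic anhydrase CA14 (-1.78 ± 0.23) and PRSS35 (-2.44 ± 0.32). Within year these differences were 2.87 for CCND2, 2.54 for HCLS1, 2.29 for WASF3, 2.00 for PLSCR4 and 1.92 for CMTM8, and -2.19, -2.85, -1.77 and -2.53 for the lower ones. Lower bounds among these, with TC-71 under 5, are the differences of HCLS1 (4.90), WASF3 (4.42) and PLSCR4 (3.78), and with TC/AEW under 5 those of SUSD5, HSD17B2 and PRSS35. From the gene lists, the tetraspanin CD9 was at least 2.16 ± 0.29 higher (1.86 within year, TC-71 at 4.52), the mTOR inhibitor DEPTOR 2.15 ± 0.53 (1.72 within year) and the matrix proteoglycan LUM 3.14 ± 1.12 (1.86 within year), for which the TC-71 samples spread widely (5.22 ± 1.51). GAP43, a protein of growth cones, differed by -2.07 ± 0.34 (-2.47 within year). None passed over all genes, with the lowest adjusted p at 0.709, and CCND2, CD9, GAP43 and CYP3A5 passed when adjusted over the list alone.

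In TC/AEW, 7 lists were called, all higher. Interferon-response genes had 22 of 24 members higher, 9 of them at least 2-fold, with a median of 0.88 (adjusted p = 1.88e-17, and adjusted p = 0.648 with an estimated correlation). IFIT2 was 2.49 ± 0.36 higher, the ubiquitin-like ligase HERC5 2.34 ± 0.35 and IFIH1, near background in TC-71, at least 2.29 ± 0.38, with 2.03, 2.01 and 1.78 within year. The count was 0 over all genes and 11 adjusted over the list alone, and the list mean was 0.98 higher pooled and 0.72 higher within year. Antigen presentation genes had 11 of 15 higher (median 0.30, adjusted p = 6.74e-05, and adjusted p = 0.648 with an estimated correlation), with the class I molecules HLA-C at 1.70 ± 0.22 (1.59 within year) and HLA-B at 1.48 (1.13 within year). Of this list 0 passed over all genes and 5 adjusted over the list alone (HLA-B, HLA-C, HLA-F, HLA-G and TAP1). Cholesterol and lipid synthesis had 22 of 25 higher (median 0.30, adjusted p = 6.74e-05, and adjusted p = 0.648 with an estimated correlation), led by INSIG1 (1.27 ± 0.31, 1.33 within year) and HMGCS1 (1.03, 1.15 within year). With no _x_at or _s_at probe sets, antigen presentation (median 0.12) and the amino acid and unfolded protein response were no longer called.

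The other 4 lists of TC/AEW had 0 members past the threshold over all genes and 0 adjusted over the list alone. Immediate early genes had 16 of 18 higher (median 0.32, adjusted p = 6.83e-04, and adjusted p = 0.648 with an estimated correlation), with the transcription factor KLF2 at 1.73, or 0.81 within year. FOXO and insulin-repressed targets had 16 of 18 higher (median 0.48, adjusted p = 0.00289, and adjusted p = 0.722 with an estimated correlation), but the list mean was 0.41 pooled and 0.10 within year, and TXNIP turned from 1.17 to -0.47. Amino acid and unfolded protein response genes had 23 of 30 higher (median 0.29, adjusted p = 0.0227, and adjusted p = 0.937 with an estimated correlation), while the list mean of 0.51 turned to -0.32 within year and VLDLR from 1.90 to -0.60. That list was not called without TC-71 sample 1 (adjusted p = 0.218) or sample 3 (0.541). Hypoxia and glycolysis genes had 25 of 30 higher (median 0.15), with a list mean of 0.20 pooled and 0.12 within year. The hypoxia list was not called without TC-71 sample 3, without TC/AEW array 2 or with the year mark as a block. Of lists not called, EWS-FLI1 repressed genes came nearest (16 of 25 higher, median 0.20, adjusted p = 0.0815), with the matricellular CCN1 at 1.29 (1.35 within year), and fibroblast and stromal markers had a mean of 0.41 (adjusted p = 0.185). The adjusted p of lists not called ran up to 0.992, and 10 differed in sign between median, mean and test, such as cell cycle inhibitors and D cyclins with a median of -0.04 and a mean of 0.18.

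For TC/AEW limma called 0 genes, with 501 at an unadjusted p under 0.05. Taking the 9 arrays as samples, which counts technical replicates as biological ones, gave 547. The averaged samples gave fewer genes at an unadjusted p under 0.05 than the share of 0.05 expected without any change. At least 2-fold apart were 317 genes, 248 higher and 69 lower. Over all genes, every array of the line lay beyond the TC-71 arrays in 29.6%. Chance puts a lone sample beyond 3 others in 50%, and less often where both arrays must lie beyond. The 29.6% cannot be set directly against 50%. Within year 276 genes were 2-fold apart, 149 higher and 127 lower, and without TC-71 sample 2 the pooled count was 549.

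TC/AVE was set against TC-71 to see what selection with AVE1642 left behind. ECI2, an isomerase of fatty acid oxidation, stood at 4.05 against 8.82 ± 0.21 in TC-71 (at least 4.77 ± 0.25 lower). The aminopeptidase ENPEP (-4.19 ± 0.26, 18.3-fold lower), RARRES2, which encodes chemerin (-3.82 ± 0.26), and the neuronal pentraxin NPTX2 (-3.90 ± 0.29) were also lower. EMP1, a membrane protein of epithelia, was at least 5.82 ± 0.56 higher, with TC/AVE at 9.65 and TC-71 near background at 3.83 ± 0.72. PDE8B, a phosphodiesterase that degrades cAMP, was 3.09 ± 0.21 higher, PLSCR4 2.83 ± 0.26 and the transcription factor SOX7 2.62 ± 0.25. The lowest adjusted p, 0.0853, was shared by ECI2, ENPEP, RARRES2 and PDE8B. Within year the lower genes differed by -5.00, -4.17, -3.72 and -4.20, EMP1 by 5.16, PDE8B by 3.12, PLSCR4 by 2.66 and SOX7 by 2.58. With TC-71 under 5 for EMP1, PLSCR4 and SOX7, and TC/AVE under 5 for ECI2 and NPTX2, these are lower bounds.

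Single neural and mesenchymal genes had low values in TC/AVE, although neither list was called. The neural list also held higher genes, such as SCG2, 2.22 above TC-71. SOX11, a neural transcription factor, stood at 5.73 against 10.02 ± 0.55 (-4.29 ± 0.45, 19.6-fold lower), and the neurofilament genes NEFM and NEFL differed by -1.94 ± 0.41 and -1.84 ± 0.31, with -3.65, -2.05 and -1.86 within year. LGALS1, which encodes galectin-1, differed by -3.42 ± 0.42, COL3A1 by -2.05 ± 0.53 and the mesenchymal homeobox gene PRRX1 by -1.95 ± 0.25, with -4.00, -2.78 and -2.12 within year. The growth factor MDK (-1.59 ± 0.22, -1.60 within year) and WNT5A (-1.71 ± 0.27, -1.49 within year) were lower too. GRB14, an adaptor that inhibits the insulin receptor, was at least 1.92 ± 0.24 higher (1.85 within year, TC-71 at 3.51) and the apoptosis inhibitor BCL2 1.39 ± 0.33 (1.31 within year). The lists themselves were mixed, with 9 of 24 neural genes higher and 15 lower (adjusted p = 0.608) and 9 of 29 mesenchymal and matrix genes higher and 20 lower (adjusted p = 0.122). Over all genes 0 members passed, and adjusted over the list alone 5 neural genes passed (CRMP1, NCAM1, NEFL, NEFM and SOX11), with PRRX1, LGALS1, GRB14, MDK and WNT5A in their lists.

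In TC/AVE, 6 lists were called, all higher. With no _x_at or _s_at probe sets only cholesterol synthesis and antigen presentation of these were called. Interferon response, immediate early genes, amino acid and unfolded protein response and ABC transporters were not. Cholesterol and lipid synthesis had 21 of 25 genes higher, 6 at least 2-fold, with a median of 0.49 (adjusted p = 6.73e-08, and adjusted p = 0.625 with an estimated correlation). INSIG1 was 1.79 ± 0.31 higher, HMGCS1 1.52 ± 0.25, the cholesterol carrier STARD4 1.37 ± 0.36 and DHCR7, which makes the last step to cholesterol, 1.34 ± 0.23, with 1.85, 1.64, 1.02 and 1.36 within year. The count was 0 over all genes and 5 adjusted over the list alone (ACSS2, DHCR7, HMGCS1, INSIG1 and MSMO1). Antigen presentation genes had 13 of 15 higher (median 0.68, adjusted p = 6.46e-06, and adjusted p = 0.625 with an estimated correlation), with the peptide transporter TAP1 at 1.16 ± 0.24 (1.03 within year), and 0 passed over all genes and 0 adjusted over the list alone. The list means were 0.55 and 0.53 higher pooled and 0.56 and 0.49 within year.

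Interferon-response genes were split in TC/AVE. Of 24, 18 were higher and 6 lower (median 0.35, adjusted p = 0.00107, and adjusted p = 0.998 with an estimated correlation). LGALS3BP, a secreted glycoprotein, was 2.11 ± 0.29 higher and IFIH1, near background in TC-71, at least 1.96 ± 0.38, while HERC5 (at least 1.51 ± 0.35, TC/AVE at 4.06) and IFI44 (-1.57 ± 0.37) were lower, with 1.78, 1.45, -1.85 and -2.06 within year. The count was 0 over all genes and 6 adjusted over the list alone. The list mean of 0.39 pooled was 0.13 within year, and the list was not called without TC-71 sample 1 (adjusted p = 0.0777). Immediate early genes had 17 of 18 higher (median 0.35, adjusted p = 8.96e-04, and adjusted p = 0.649 with an estimated correlation), with KLF2 at 1.59 (0.67 within year) and KLF6 at 1.10 (0.73 within year). ABC and drug transporters had 11 of 16 higher (median 0.21, adjusted p = 0.0325, and adjusted p = 0.981 with an estimated correlation), with ABCA5 at 0.96 (0.87 within year), and were not called without TC-71 sample 2 (0.211) or TC/AVE array 1 (0.0524). Amino acid and unfolded protein response genes had 25 of 30 higher (median 0.39, adjusted p = 0.0252, and adjusted p = 0.998 with an estimated correlation), but the list mean of 0.43 turned to -0.41 within year and CHAC1 from 0.96 to -1.03. That list was not called without TC-71 sample 1 (0.195) or sample 3 (0.537). In the last 3 lists 0 passed over all genes and 0 adjusted over the list alone. Lists not called had adjusted p up to 0.999, and 9 differed in sign between median, mean and test, such as xenobiotic and glutathione metabolism with a median of 0.05 and a mean of -0.03.

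For TC/AVE limma called 0 genes, with 1018 at an unadjusted p under 0.05. Taking the 9 arrays as samples gave 1857 and cyclic loess normalisation gave 4. At least 2-fold apart were 527 genes, 281 higher and 246 lower. Over all genes, every array of the line lay beyond the TC-71 arrays in 39.3%. The chance share is 50% for a lone sample and lower where both arrays must lie beyond, so the 2 cannot be compared directly. Within year 578 genes were 2-fold apart, 202 higher and 376 lower.

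**Figure D2:**
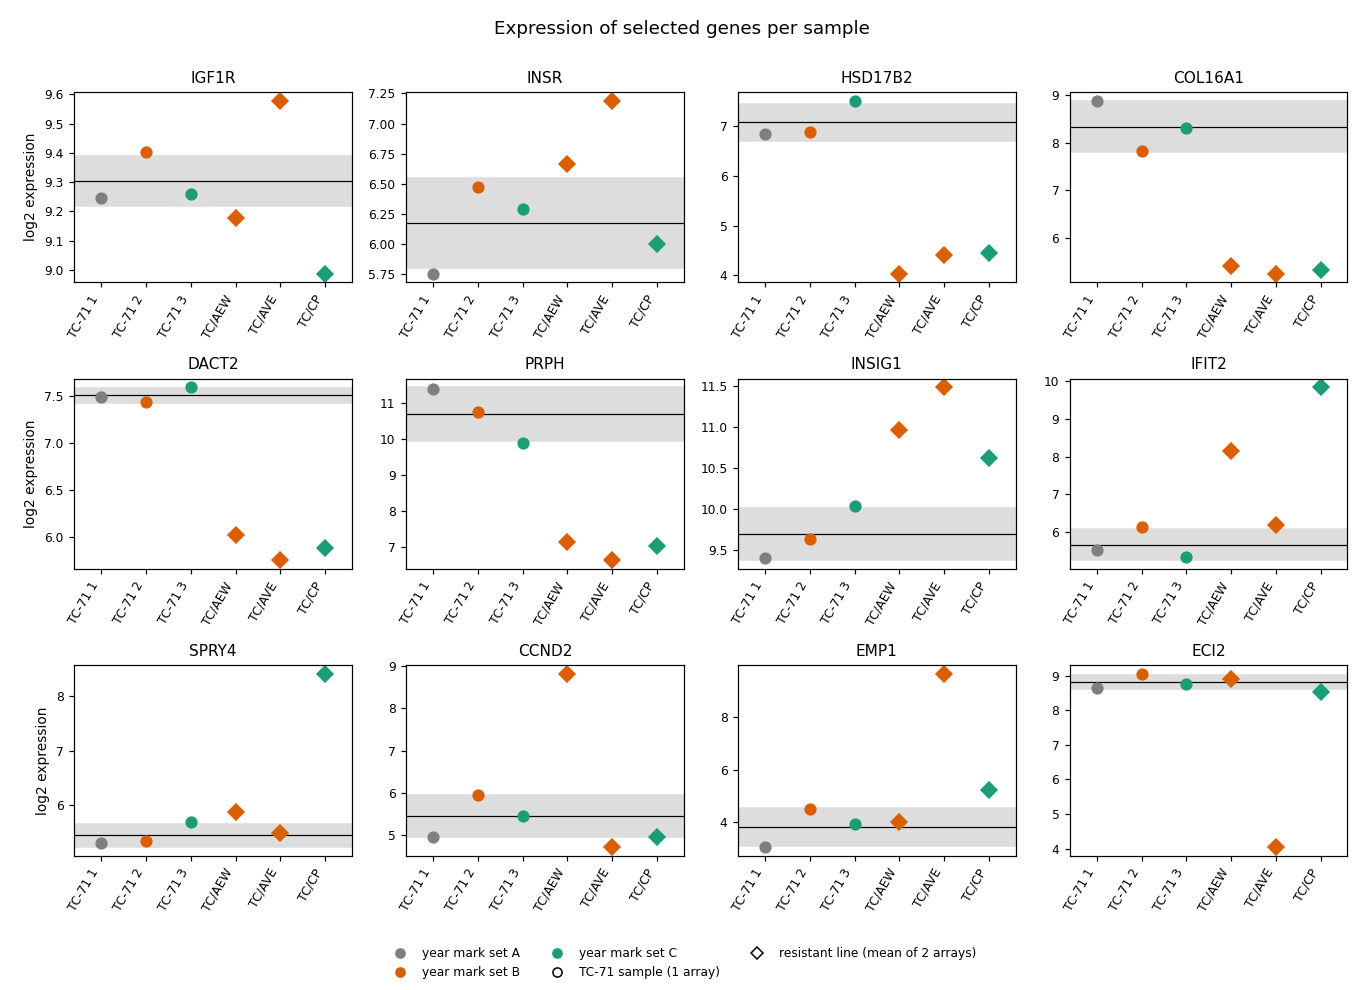
Log2 expression of 12 genes in each of the 6 samples, with colour giving the year mark set, the line the TC-71 mean and the grey band its SD. HSD17B2, COL16A1 and DACT2 lay below TC-71 in all 3 lines, while SPRY4 stood out in TC/CP (8.42), CCND2 in TC/AEW (8.82) and EMP1 and ECI2 in TC/AVE (9.65 and 4.05).

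TC/CP was set against TC-71 to see what selection with figitumumab left behind. Messages that follow ERK activity were higher in it. SPRY4, a feedback inhibitor of receptor tyrosine kinases, stood at 8.42 against 5.43 ± 0.21 in TC-71 (2.99 ± 0.26 higher, 7.94-fold). FOSL1, an AP-1 transcription factor, was 2.39 ± 0.22 higher, the ERK phosphatase DUSP6 2.18 ± 0.47, ETV1 1.94 ± 0.73 and the receptor EPHA2 1.43 ± 0.23. Of the 27 genes of the ERK output list, 22 were higher and 5 lower, with 10 at least 2-fold higher and a median of 0.42 (adjusted p = 4.71e-08, and adjusted p = 0.841 with an estimated correlation). The count was 0 over all genes and 4 adjusted over the list alone (DUSP6, EPHA2, FOSL1 and SPRY4). The list mean was 0.78 higher pooled and 0.75 within year, and SPRY4, FOSL1 and DUSP6 differed by 2.74, 2.25 and 2.45 within year, with ETV1 at 1.63 and EPHA2 at 1.26.

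Interferon-response genes were also higher in TC/CP, in 21 of 24 members, with a median of 0.54 (adjusted p = 2.15e-08, and adjusted p = 0.865 with an estimated correlation). IFIT2 stood at 9.84 against 5.66 ± 0.41 (4.18 ± 0.36 higher, 18.1-fold), IFIT3 was 3.24 ± 0.52 higher, IFIT1 2.76 ± 0.55 and HERC5 2.11 ± 0.35, with 4.51, 3.26, 3.00 and 2.01 within year. The count was 0 over all genes and 6 adjusted over the list alone, and the list mean was 0.86 higher pooled and 0.87 within year. Hypoxia and glycolysis genes had 25 of 30 higher (median 0.20, adjusted p = 0.00121, and adjusted p = 0.865 with an estimated correlation), with the glucose transporter SLC2A3 at 1.08 (1.29 within year) and the enolase ENO2 at 0.94 (0.89 within year). Mitochondrial respiratory chain genes had 24 of 33 lower (median -0.11), with a list mean of -0.12 pooled and -0.08 within year. NDUFA2 differed by -0.53 (-0.42 within year). The respiratory chain list was not called without TC-71 sample 2, without TC/CP array 2 or with the year mark as a block. In these 2 lists 0 passed over all genes and 0 adjusted over the list alone. Antigen presentation genes, in contrast to the other lines, had a mean of 0.02, and cholesterol synthesis stood at a median of 0.21 with 17 of 25 higher (adjusted p = 0.0901).

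The genes ranked first in TC/CP were NT5E, the ecto-enzyme CD73 that makes adenosine (6.55 against 3.45 ± 0.01 in TC-71), and FERMT3, an activator of integrins (2.60 ± 0.22). Lowest were DSCR8 (-3.15 ± 0.27), SUSD5 (-2.28 ± 0.23), the matrix protein MFAP4 (-2.06 ± 0.21) and the peptide hormone APELA (-2.45 ± 0.28). The neural genes SCG2 (3.24 ± 0.63), NEFM (1.70 ± 0.41) and nestin (NES, 1.54 ± 0.38) had higher values, as did the matrix genes TNC (2.44 ± 0.48), COL1A1 (1.24 within year) and COL4A1 (1.46 ± 0.25). The adhesion molecule NRCAM was 2.25 ± 0.40 higher, the receptor RET 1.98 ± 0.24 and GCLM, which limits glutathione synthesis, 1.83 ± 0.23, while SMAD9, a BMP effector, differed by -1.47 ± 0.20. Of these, SCG2, NEFM, NES, TNC, COL1A1, COL4A1, RET, GCLM and SMAD9 passed when adjusted over the list alone and 0 passed over all genes, with the lowest adjusted p at 0.224. Within year NT5E differed by 3.09, FERMT3 by 2.59, SCG2 by 3.25, NEFM by 1.27, NES by 1.54, TNC by 2.05, COL4A1 by 1.39, NRCAM by 2.68, RET by 1.83, GCLM by 1.73, SMAD9 by -1.50, DSCR8 by -2.90 and APELA by -2.63. The differences of NT5E and COL4A1, under 5 in TC-71, and of DSCR8 and SUSD5, under 5 in TC/CP, are lower bounds. Neural genes as a list had 13 of 24 higher and mesenchymal and matrix genes 16 of 29 (median 0.02), both with adjusted p = 0.384. Lists not called had adjusted p up to 0.985, and 4 differed in sign between median, mean and test, such as other receptor tyrosine kinases with a median of -0.02 and a mean of 0.07.

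For TC/CP limma called 0 genes, with 705 at an unadjusted p under 0.05. Taking the 9 arrays as samples gave 1029 and a mean-variance trend gave 1. The averaged samples gave no more genes at an unadjusted p under 0.05 than the share of 0.05 expected without any change. At least 2-fold apart were 457 genes, 345 higher and 112 lower. Over all genes, every array of the line lay beyond the TC-71 arrays in 38.0%. The chance share is 50% for a lone sample and lower where both arrays must lie beyond, so the 2 cannot be compared directly. Within year 340 genes were 2-fold apart, 234 higher and 106 lower.

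TC/AEW was then set against the mean of the 2 antibody-selected lines, to separate the kinase inhibitor from the antibodies. CCND2 stood at 8.82 in TC/AEW and at 4.72 and 4.95 in TC/AVE and TC/CP, near background, so the difference of 3.99 ± 0.44 is a lower bound. HCLS1 was 3.04 ± 0.28 higher. ECI2 (2.62 ± 0.27) ranked next through its low level in TC/AVE alone, and NXN, a redox regulator of WNT signalling, was 2.09 ± 0.23 higher. Lower in TC/AEW were the flippase ATP8B1 (4.64 against 7.55 and 7.93), the nitric oxide synthase NOS1 (-2.40 ± 0.32), the lipid-presenting CD1D (-1.75 ± 0.28) and NT5E (-1.54 ± 0.21), the last through TC/CP alone. Within year these genes differed by 3.74, 2.96, 2.48, 2.09, -3.42, -2.63, -1.57 and -1.53. LUM was 3.78 ± 1.19 higher (3.33 within year) and GAP43 differed by -2.06 ± 0.36 (-2.29 within year). Pooled differences were lower bounds also for HCLS1, ECI2 and LUM, under 5 in TC/AVE, and for ATP8B1 and CD1D, under 5 in TC/AEW. NT5E lay under 5 in both TC/AEW and TC/AVE, which leaves its difference without a bound.

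Against the antibody-selected lines, 3 lists were called. Interferon-response genes had 20 of 24 higher in TC/AEW (median 0.28, adjusted p = 4.5e-05, and adjusted p = 0.904 with an estimated correlation), led by HERC5 at 2.05 ± 0.37, a lower bound since TC/AVE lay under 5, with a list mean of 0.35 pooled and 0.22 within year. By list mean the contrast lay with TC/AVE, with 0.98 above TC-71 in TC/AEW, 0.39 in TC/AVE and 0.86 in TC/CP. Within year the mean of TC/CP (0.87) exceeded that of TC/AEW (0.72). By median TC/AEW (0.88) lay above both TC/AVE (0.35) and TC/CP (0.54), and within year the medians were 0.71, 0.07 and 0.41. Between TC/AVE and TC/CP 11 members were higher and 13 lower, so the contrast cannot be placed on 1 antibody-selected line. FOXO and insulin-repressed targets had 15 of 18 higher (median 0.38, adjusted p = 0.00531, and adjusted p = 0.904 with an estimated correlation), with TXNIP at 1.70 pooled and 0.38 within year and the list mean at 0.38 and 0.19. ERK output genes had 18 of 27 lower (median -0.15, adjusted p = 0.0476, and adjusted p = 0.904 with an estimated correlation), with DUSP5 at -1.13 ± 0.35 and SPRY4 at -1.09 ± 0.27, and with a list mean of -0.21 pooled and -0.24 within year. Here the contrast lay with TC/CP, since the list stood 0.25 above TC-71 in TC/AEW, 0.14 in TC/AVE and 0.78 in TC/CP (within year 0.16, 0.05 and 0.75). The ERK list was not called without TC-71 sample 1 (0.0878) or sample 3 (0.0566), or without TC/AEW array 2 (0.0876), TC/AVE array 1 (0.0673) or TC/CP array 2 (0.0737). In the 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. HLA-C, CCND2 and IGFBPL1, an IGF-binding protein relative (1.06 higher, 1.07 within year, with TC-71 and the antibody-selected lines under 5), passed when adjusted over lists that were not called. Lists not called had adjusted p from 0.0809 to 0.949, and 7 differed in sign between median, mean and test. Over all genes limma called 0, with a lowest adjusted p of 0.686 and 263 genes at an unadjusted p under 0.05, and taking the 9 arrays as samples gave 295. The averaged samples gave fewer genes at an unadjusted p under 0.05 than the share of 0.05 expected without any change. At least 2-fold apart were 189 genes, 142 higher and 47 lower in TC/AEW, and 184 within year.

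The 2 antibody-selected lines were compared with each other, since both antibodies bind the same receptor. TC/AVE had higher PDE8B (3.43 ± 0.25), PPP1R14C, an inhibitor of protein phosphatase 1 (2.80 ± 0.27), the astrocytic membrane protein MLC1 (3.39 ± 0.33) and DSCR8 (3.30 ± 0.33). It had lower ECI2 (-4.48 ± 0.31), NT5E (-3.21 ± 0.25), FERMT3 (-3.32 ± 0.27) and PIWIL2, a germline Argonaute protein (-2.93 ± 0.27). Of 24 neural genes 12 were higher and 12 lower (median -0.01, adjusted p = 0.143), but NEFM stood at 6.28 in TC/AVE and 9.92 in TC/CP (-3.64 ± 0.51), with NEFL at -3.13 ± 0.38 and SOX11 at -3.27 ± 0.55. IFIT2 (-3.66 ± 0.44) and HERC5 (-3.62 ± 0.43) were lower, although the interferon list as a whole had 11 of 24 members higher and 13 lower (adjusted p = 0.457). INPP4B, a phosphatase of phosphoinositides, differed by -3.03 ± 0.88 and RET by -2.12 ± 0.30. Within year the first 8 genes differed by 3.42, 2.99, 3.26, 2.79, -4.77, -3.19, -3.17 and -2.70, NEFM by -3.33, NEFL by -2.83, SOX11 by -2.32, IFIT2 by -4.45, HERC5 by -3.85, INPP4B by -4.58 and RET by -1.77. Pooled differences are lower bounds for ECI2, NT5E, HERC5 and INPP4B, under 5 in TC/AVE, and for PDE8B and DSCR8, under 5 in TC/CP.

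Between TC/AVE and TC/CP, 6 lists were called. Antigen presentation was higher in TC/AVE in 13 of 15 genes (median 0.69, adjusted p = 5.0e-05, and adjusted p = 0.568 with an estimated correlation), with TAP1 at 1.01 ± 0.30. Cholesterol and lipid synthesis was higher in 21 of 25 (median 0.31, adjusted p = 3.21e-04, and adjusted p = 0.568 with an estimated correlation), with DHCR7 at 1.15 ± 0.28. ERK output was lower in 22 of 27 (median -0.46, adjusted p = 2.39e-04, and adjusted p = 0.568 with an estimated correlation), with SPRY4 at -2.95 ± 0.31, EPHA2 at -2.47 ± 0.28 and DUSP6 at -2.44 ± 0.58. Mesenchymal and matrix genes were lower in 18 of 29 (median -0.37, adjusted p = 0.00701, and adjusted p = 0.643 with an estimated correlation), with COL4A2 at least 2.14 ± 0.30 lower, since TC/AVE lay under 5. These 4 lists had within-year means of 0.44, 0.32, -0.71 and -0.62. Mitochondrial respiratory chain genes were higher in 26 of 33 (median 0.29, adjusted p = 9.55e-04, and adjusted p = 0.897 with an estimated correlation), with NDUFV1 at 0.84 ± 0.26 and a list mean of 0.22 pooled and 0.05 within year. Amino acid and unfolded protein response genes were higher in 28 of 30 (median 0.56, adjusted p = 2.39e-04, and adjusted p = 0.897 with an estimated correlation), but the list mean of 0.66 turned to -0.62 within year and VLDLR from 2.15 to -1.67. Over all genes 0 members of the 6 lists passed, and adjusted over the list alone 3 ERK output genes (EPHA2, FOSL1 and SPRY4) and 5 matrix genes (COL1A1, COL4A1, COL4A2, LAMC1 and PRRX1) passed. Lists not called had adjusted p from 0.0762 to 0.961, and 7 differed in sign between median, mean and test.

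For TC/AVE against TC/CP limma called 0 genes, with a lowest adjusted p of 0.221 and 816 at an unadjusted p under 0.05. Taking the 9 arrays as samples gave 1897 and a mean-variance trend gave 1. At least 2-fold apart were 674 genes, 214 higher and 460 lower in TC/AVE. These 2 lines carried different year marks, and 767 genes were 2-fold apart when each was set against its own TC-71 sample.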

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

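The tests on year marks, immune markers and extreme list members were chosen after the results were seen, while the other splits of the samples were planned before. The 9 results for gene lists below, 2 of them for ERK output, were singled out by a direct test by camera. In that test 2 resistant lines, or TC/AEW and the pair of antibody-selected lines, differed from each other.

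Against the antibody-selected lines, TC/AEW had a median log2 difference of 0.28 for interferon-response genes, 0.38 for FOXO and insulin-repressed targets and -0.15 for ERK output. Between TC/AVE and TC/CP the medians were 0.69 for antigen presentation, -0.46 for ERK output, 0.56 for amino acid and unfolded protein response genes, 0.31 for cholesterol and lipid synthesis, 0.29 for the mitochondrial respiratory chain and -0.37 for mesenchymal and matrix genes. Within year the medians were 0.38, -0.48, -0.41, 0.38, 0.09 and -0.50 in the same order, so the amino acid list turned and the respiratory chain shrank, and TC/AVE and TC/CP carry different year marks. With an estimated correlation none of the 9 was called. In simulations of a single line that test called 0% of lists raised by 0.5. For the interferon, FOXO, amino acid and respiratory chain lists, the estimated correlation was above the preset 0.01. Their lost calls cannot tell gene correlation from lack of power. For ERK output (-0.02), antigen presentation (-0.03), cholesterol synthesis (-0.02) and mesenchymal genes (-0.01) it was under 0.01, which argues against gene correlation as the cause. The agent used for selection is one explanation of these differences and stays untested, since each agent was used on 1 line. Chance divergence between lines grown apart for 6 months stays open on the same ground.

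For the lines in common, the 10 splits of the 6 samples into 3 and 3 were too few for a share under 0.05. The real split called 3 genes and the highest of the others 0, so 1 of the 10 splits gave as many. It called 6 lists and the highest of the others 6, in the splits that set TC-71 samples 1 and 2 with TC/CP, or TC-71 samples 1 and 3 with TC/AVE, against the rest, so 3 of the 10 gave as many. The split that followed the year marks, TC-71 samples 1 and 3 with TC/CP against TC-71 sample 2 with TC/AEW and TC/AVE, called 0 genes and 5 lists by limma. It had 1810 genes at an unadjusted p under 0.05 against 1187 in the real split, a structure of the samples that the groups do not describe.

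The first pattern weighed was the higher amino acid and unfolded protein response in TC/AEW and TC/AVE. TC-71 sample 2, of the same year mark, lay 0.83 above the TC-71 mean, higher than either line. The higher of the 2 lines was -0.32 from that sample, where a difference between 2 TC-71 samples has an SD of 1.02, so the pooled difference may come from what set those arrays apart, and the list should not be read as a mark of resistance. Whether culture state or array handling lay behind the year mark cannot be separated with 1 TC-71 sample per mark, and no biological explanation was tested.

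The next was the higher interferon response. In TC/CP the within-year difference of the list mean was 0.87, against 0.86 pooled. This exceeded 50% of the pooled value by more than the SD of 0.36 for a difference between 2 TC-71 samples. The rise thus held against the TC-71 sample of the same mark, but 1 such sample cannot exclude the year mark. In TC/AEW the within-year difference was 0.72 against 0.98 pooled, beyond 50% by less than that SD, so the year mark stays open there too. In TC/AVE it was 0.13 against 0.39 pooled, which the year mark could explain. RNA from blood and immune cells was weighed by 9 markers, although all samples were cell lines kept in culture, with no known source of such cells. In TC/CP 0 of the 9 markers were higher than the TC-71 mean and 9 lower. Their mean was -0.15 there, with an SD of 0.12 between TC-71 samples, which argues against such RNA in that line. In the higher line, TC/AEW, the mean lay -0.0374 from the highest TC-71 sample, within that SD, so the markers do not decide there. Only CD2 and CD3D lay under 5 in any sample, and the markers cannot exclude a small share. Over the 6 samples the markers lay between 4.38 (CD2) and 6.91 (AIF1), with CD79A at 6.40 and AIF1 at 6.80 in TC/AEW against 6.79 and 6.91 in the highest TC-71 samples.

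The last was the higher ERK output in TC/CP. Its within-year difference was 0.75 against 0.78 pooled, with an SD of 0.15 for a difference between 2 TC-71 samples. The rise thus held against the TC-71 sample of the same mark, but 1 such sample cannot exclude the year mark. Without the 4 members with the largest differences the other 23 were still higher by camera in limma (p = 2.74e-05, and 0.0436 with an estimated correlation, both unadjusted), which argues against 1 or 2 extreme genes as its cause. A hypothesis left open is that TC/CP signals more through ERK, seen in 1 line only. Phosphorylated ERK in TC/CP against TC-71 would test it and was not measured here.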

How the results depend on the processing

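Every alternative was chosen before the data were examined, except the within-year difference for gene lists. The filter, probe set, loess and trend settings were planned for genes and applied to lists as well. Of the results for named genes, 3865 stayed the same under an alternative, 400 became significant and 28 stopped being so. A further 123 moved, some of them in sign, and 8 reversed with a call under the alternative. Staying the same meant keeping direction and side of the threshold. For the within-year difference, which has no test, it meant lying within the SE of the main value for genes and keeping direction for lists. Of the 226 named gene results, 35 changed sign in at least 1 alternative, 8 of them with a difference of at least 1 on the log2 scale. Of those for gene lists, 575 stayed the same, 83 stopped being called and 6 reversed. Where no cause is given, the cause was not tested.

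Single-line comparisons called 0 genes by limma when each array or TC-71 sample was left out. They called 6 for TC/AVE with the mean of a gene's probe sets and 4 with cyclic loess, and a mean-variance trend called 1 for TC/CP and 1 for TC/AVE against TC/CP. For the lines in common the count of 3 became 0 with no filter on dim probe sets. It was 6 where 2 of 9 arrays had to reach 6 and 6 with the mean of the gene's probe sets. With no _x_at or _s_at probe sets it was 5, and with the trend 6. As a contrast in the 4-group fit it was 0, and with duplicateCorrelation over the RNA source 67. Leaving out a sample, array or line gave 0 to 5. The value was 0 without TC-71 sample 1, 2 or 3 and without any line, where fewer samples remained. COL16A1, DACT2 and HSD17B2 were among the genes called in the settings that called 4, 5, 6, 39, 67 and 240.

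Taking the 9 arrays as samples called 547 genes in TC/AEW, 1857 in TC/AVE, 1029 in TC/CP, 240 in the lines in common, 295 between TC/AEW and the antibody-selected lines and 1897 between TC/AVE and TC/CP, with 155 in all 3 lines in 1 direction. By construction this counts technical replicates as biological ones. With a replicate block added, pairing arrays by number, the counts were 350, 1220, 1242, 39, 238 and 1798, with 133 in all 3 lines. Across genes, the difference between array 1 and array 2 correlated at 0.20 between TC/AEW and TC/AVE, -0.12 between TC/AEW and TC/CP and -0.15 between TC/AVE and TC/CP, so the numbers did not pair the arrays throughout.

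With the year mark as a block the counts were 2625 in TC/AEW, 4667 in TC/AVE, 2401 in TC/CP, 1590 between TC/AEW and the antibody-selected lines and 3070 between TC/AVE and TC/CP, with 555 in all 3 lines. That fit has only technical replicates to estimate the residual, so these counts are not evidence of change. For the lines in common, where samples gave the residual, the count was 0. The block reversed 8 genes: TXNIP (-0.47), VLDLR (-0.60) and ATF3 (-0.58) in TC/AEW, ASNS (-0.56) and CHAC1 (-1.03) in TC/AVE, and VLDLR (-1.67), CHAC1 (-1.84) and ASNS (-0.75) between TC/AVE and TC/CP. It also reversed the median of the amino acid and unfolded protein response list, to -0.36 in TC/AEW, -0.38 in TC/AVE and -0.41 between TC/AVE and TC/CP, as did the within-year difference. By construction both set each line against the TC-71 sample of its own year mark in place of the TC-71 mean.

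With an estimated correlation 0 lists were called in each of the 6 comparisons, against 7, 6, 4, 6, 3 and 6. In simulations that test called 0% of lists raised by 0.5 in a single line and 85% in the lines in common. Differences between the lines were not simulated, so the 85% may be too high. In the 4-group fit the estimated correlation was above the preset 0.01 for interferon (0.36), amino acid (0.45), respiratory chain (0.49), FOXO (0.10) and ABC transporter genes (0.12). There the lost calls cannot tell gene correlation from lack of power. For the other lists called in that fit, such as ERK output (-0.02) and cholesterol synthesis (-0.02), it was under 0.01. This argues against gene correlation as the cause of their lost calls. The count of lists for TC/AEW was 11 where 2 of 9 arrays had to reach 6. That for TC/AEW against the antibody-selected lines was 5 with the mean of the gene's probe sets. With no _x_at or _s_at probe sets the count was 2 for TC/AVE and 3 for the lines in common. The year mark block also ended the calls of FOXO targets (adjusted p = 0.439) and hypoxia (0.171) in TC/AEW, interferon in TC/AVE (0.414) and the mitochondrial respiratory chain in TC/CP (0.215). Leaving out 1 array or sample gave 5 to 8 lists for TC/AEW, 4 to 7 for TC/AVE, 3 to 5 for TC/CP, 4 to 8 for the lines in common, 2 to 4 for TC/AEW against the antibody-selected lines and 6 to 7 for TC/AVE against TC/CP.

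On leaving out 1 array, sample or line, the count of genes at least 2-fold apart ran from 240 to 549 in TC/AEW and from 174 to 376 in the lines in common, with the highest values without TC-71 sample 2. It ran from 474 to 707 in TC/AVE, 366 to 585 in TC/CP, 185 to 209 for TC/AEW against the antibody-selected lines and 674 to 691 between TC/AVE and TC/CP. Signal over background limits what can be seen of dim genes, which the filter at 5 leaves out.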

Other observations

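The test on neighbouring genes was planned before its result was seen, while its count of separate runs was added after, and the genes below were chosen after their values were seen. Among genes at least 2-fold higher in all 3 lines were MLKL, the effector of necroptosis (2.33 ± 0.43 in the lines in common), the kinase PRKD1 (2.12 ± 0.39), TRIM14, an adaptor of antiviral signalling (2.07 ± 0.34), BACE2, a membrane protease (1.68 ± 0.25), and MICB, a stress ligand for natural killer cells (1.47 ± 0.25). Among those at least 2-fold lower were the amino acid transporter SLC38A4 (-2.53 ± 0.40), the cytidine deaminase APOBEC3B (-2.09 ± 0.32), STEAP1B (-1.68 ± 0.17), and 2 genes of collagen processing, RCN3 (-1.62 ± 0.21) and PCOLCE (-1.59 ± 0.30). The nearest to the threshold were STEAP1B and PRPH, both at adjusted p = 0.0526, with CA14 (-1.92 ± 0.20) at 0.0618. Because the 3 lines share their TC-71 samples, some agreement between them arises without any change. Within year the differences in the lines in common were 2.36 for MLKL, 1.88 for PRKD1, 1.61 for TRIM14, 1.75 for BACE2, 1.44 for MICB, -2.94 for SLC38A4, -2.33 for APOBEC3B, -1.54 for STEAP1B, -1.50 for RCN3, -1.50 for PCOLCE and -1.87 for CA14. The differences of MLKL, under 5 in TC-71, and of SLC38A4, APOBEC3B and STEAP1B, under 5 in the lines, are lower bounds.

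Runs of neighbouring genes shifted together in the resistant lines and in TC-71. Gene order was taken from a RefSeq table for assembly GRCh38.p14, in 13697 windows of 20 genes. The windows with a median beyond the 95th percentile of the maximum over 100 permutations numbered 121 in TC/AEW, 142 in TC/AVE and 197 in TC/CP, against 21, 67 and 2 for TC-71 samples 1, 2 and 3, each set against the other 2. Within year the lines had 88, 128 and 283. Because windows overlap, these fell into 10, 11 and 13 separate runs in TC/AEW, TC/AVE and TC/CP, 4, 9 and 1 in the TC-71 samples, and 3, 15 and 12 in the lines within year, with 76 of the 88 windows of TC/AEW in 1 run. The direction of the windows depended on the TC-71 samples used, with 45 above and 76 below in TC/AEW turning to 0 and 88 within year, 101 and 41 in TC/AVE to 25 and 103, and 185 and 12 in TC/CP to 178 and 105. In TC/CP, 85 of 89 genes from SH3GLB1 to EPS8L3 were higher, with a median of 0.73 (0.70 within year). In TC/AEW, 82 of 95 genes from MICOS10P1 to OR7E156P were lower, with a median of -0.40 (-0.44 within year), and the medians there were -0.30 in TC/AVE and -0.32 in TC/CP. Of the higher runs in TC/AEW, that from PLEKHA3 to TMEFF2 had a median of 0.33 pooled and 0.05 within year. A gain or loss of chromosome segments in the lines may account for the runs that stayed within year, but the test left it open. The line with fewest windows had 121 against 67 in the TC-71 sample with most, yet by separate runs within year TC/AEW had fewer than TC-71 samples 1 and 2. This is a hypothesis from RNA alone, and shared regulation of neighbouring genes was not tested.

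IGF2 was read by 3 probe sets shared with INS-IGF2. The first stood at 4.95, 5.16 and 4.87 in the TC-71 samples, 5.81 in both TC/AEW arrays, 4.88 and 4.65 in the TC/AVE arrays and 6.09 and 5.85 in the TC/CP arrays. The other 2 lay between 4.88 and 5.54 in all arrays. IGF2 was not tested as a gene, but these probe sets were among those with no symbol or several that were tested apart.

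The 5977 probe sets with no symbol or several that passed the filter were tested apart by limma, and 0 passed in each comparison. At an unadjusted p under 0.05 there were 129 in TC/AEW, 287 in TC/AVE, 156 in TC/CP, 340 in the lines in common, 57 between TC/AEW and the antibody-selected lines and 227 between TC/AVE and TC/CP.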
